A study of Homo sapiens with 2 samples.

How the data were processed

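Total RNA of FaDu and UM-SCC-23 cells carrying a miR-34a lentivirus or the empty eGFP lentivirus was amplified through T7 transcription, labelled by random-primed reverse transcription with Cy5 (miR-34a cells) or Cy3 (control cells) and hybridised to 1 array per line, per the labels' protocols. The stable cells had been selected by flow cytometry, per the labels. The deposited scanner tables hold linear intensity values from LuxScan, per the file headers, as foreground and local background for each of 23232 spots at 635 nm (Cy5) and 532 nm (Cy3), in 48 blocks. The same deposited tables give the ratio of the 635 nm to the 532 nm foreground and its log10, per the file headers; neither column was used for the results. The authors also deposited a table of processed values, whose normalization is not given in the sources used here. Set against the scanner values, the authors' deposited values were linear Cy5 over Cy3 ratios with medians of 1.009 (FaDu) and 1.007 (UM-SCC-23); their log2 had a Pearson correlation with the log2 ratios computed here of 0.986 and 0.987.

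Foreground and background medians were corrected with normexp (offset 50) and normalized by global loess within each array in limma 3.58.1, under R 4.3.3 with the data.table package (1.17.8); the 1519 control spots had weight 0 in the loess and were then left out. A spot counted as measured where the foreground median exceeded the background median by more than 2 background standard deviations in both channels. The median signal and background over the gene spots were 64 and 40 in Cy5 and 226 and 190 in Cy3 for FaDu, and 72.5 and 42 in Cy5 and 269 and 235.5 in Cy3 for UM-SCC-23. A further 928 FaDu and 1505 UM-SCC-23 gene spots were above background in Cy5 alone, and 583 and 145 in Cy3 alone; such genes have no ratio here. Saturated spots were kept: 6 in Cy5 and 2 in Cy3 in FaDu, and 9 and 1 in UM-SCC-23; RPL8 was saturated in both lines. Detected probes of a gene were averaged. Genes with 2 to 9 detected probes numbered 34 in FaDu and 31 in UM-SCC-23, their probes spanned a median of 0.40 and 0.21 (log2), and in 6 and 5 of them the span exceeded 1.

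Gene names came from the name column of the scanner tables, updated through a RefSeq gene table of GRCh38.p14, which was used for names, neighbouring genes and gene length. Of the gene spots, 8939 carried a current symbol, 2007 an older symbol that was updated and 1821 a protein accession that matched; 1327 kept the name in the file, 5 had a name turned into a date and 7614 had no name.

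Each line's ratios were described by a size rule of 2-fold, with no test. The mean ratio over the 2 lines was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05 over 3849 genes. Nothing in the labels says that cells of a line came from separate cultures. The p-values measure the spread between 2 lines, which limma pooled to a common value for all genes. Relations between lines were computed across genes with no p-value. For 27 gene lists, the median ratio was given per line with its percentile among 10000 random lists of the same size matched on mean intensity in 20 bins (seed 34), where at least 3 members were measured. The lists cover literature targets of miR-34a, p53 targets, G1/S and G2/M genes, epithelial and keratinocyte genes, epithelial-mesenchymal transition, proteases, interferon, NF-kB, HLA, WNT, NOTCH, stem cell, hypoxia, stress, heat shock, NRF2, lipid synthesis, ribosomal, apoptosis, immediate early, housekeeping and histone genes, and markers of 3 other kinds of cells. Named genes were the 12 highest and 12 lowest per line and the 12 higher in both and the 12 lower in both with the largest smaller ratio, among genes with a symbol, measured, and above the median intensity, plus up to 4 members of each list by mean ratio and 14 fixed genes, of which NOTCH1 had no spot under that name. Groups, lists, tests, the naming rule and most alternatives were chosen before the data were examined.

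On simulated arrays with 200 changed genes, the noise was that of the replicate spots (log2 standard deviation 0.102 in FaDu and 0.0611 in UM-SCC-23) with a small added term. At this noise a true log2 change of 2 was bound to pass 2-fold, and did so for 100% of genes on both arrays. A true change of 1 passed for 32.3% in the FaDu case (4146 genes) and 24.4% in the UM-SCC-23 case (4090 genes). Differences between cultures and the trend with gene density were not simulated. For the limma mean (3849 genes), the spread between lines was that seen here, but the lines were drawn as independent. There, 37% of changes of 2 and 3% of changes of 1 were called, with 2 false calls. Alternatives covered the background correction, normalization, filter on dim probes, size rule, prior of the test and the authors' table. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.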

Results

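Messenger RNA levels were compared between cells that stably carried a lentivirus for the microRNA miR-34a and cells that carried the empty eGFP lentivirus, in 2 squamous carcinoma lines of the head and neck. FaDu is a line from the pharynx and UM-SCC-23 a line from the larynx. Each line was measured on 1 two-colour array, with the miR-34a cells in the Cy5 channel and the control cells in the Cy3 channel, so that each of the 2 groups holds 1 sample. Of 21713 gene spots, 4517 (20.8%) were above background in both channels in FaDu and 4542 (20.9%) in UM-SCC-23. The median background-subtracted intensity of these spots was 1302 in Cy5 and 1615 in Cy3 in FaDu, and 1430 and 1487 in UM-SCC-23. No line had a replicate array, and the number of arrays limits the precision. Spots printed repeatedly for each of 6 genes had a pooled standard deviation of 0.102 (log2) in FaDu and 0.0611 in UM-SCC-23, which covers spot error alone. These were bright genes, with mean log2 intensity from 10.89 (EIF4A2) to 15.57 (GAPDH) in FaDu, so the error of dim spots is not covered. All ratios are log2 of miR-34a cells over control cells. No dye-swapped array was among those analysed, so a gene-specific dye effect is contained in each ratio.

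The FaDu comparison asked which transcripts differ when miR-34a is added to these cells. Genes of the unfolded protein and amino acid stress response, of the inflammatory cytokine response and of the immediate early response were lower in the miR-34a cells. Among symbol genes above the median intensity, the stress-inducible growth arrest gene GADD45A had the lowest ratio at -4.07, followed by the cyclin CCNA1 at -4.0 and the cytokine IL1A at -3.35. On the higher side, the keratin KRT15 was at 2.76, and among symbol genes above the median intensity RIN1, a RAS effector, was highest at 2.66, followed by the collagenase MMP1 at 2.37. Of 4387 genes measured, 633 were lower and 261 higher by 2-fold or more, and 85 were lower and 13 higher by 4-fold or more.

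In the unfolded protein and amino acid stress list, 11 of 14 measured members were lower by 2-fold or more in FaDu and 1 was higher. The list median was -2.41, at the 0th percentile of 10000 random lists of like intensity. The chaperone HSPA5 stood at -3.26, the mTORC1 inhibitor DDIT4 at -3.26, SESN2 at -3.23, and the transcription factors ATF3 and XBP1 at -2.90 each. TRIB3, a target of ATF4, was at -2.61, and VEGFA, which is also on the hypoxia list, was at -2.73. NF-kB targets and inflammatory cytokines had 8 of 9 members lower by 2-fold or more and a median of -2.39, likewise at the 0th percentile; with no filter on dim probes the median was -0.70, also at the 0th percentile. IL6 stood at -3.09, IL1B at -2.66, and NFKBIA, the inhibitor of NF-kB, at -2.40. Immediate early genes, which respond to growth factors, had a median of -0.89 (percentile 0.17), with 6 of 13 lower by 2-fold or more, but -0.49 with median centring over all probes and -0.28 with no filter on dim probes. The EGF receptor ligand AREG was at -3.32, MYC at -1.43 and IER3 at -1.25.

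The NRF2 and oxidative stress list had a FaDu median of -0.76 (percentile 0.64), and 5 of its 12 measured members were lower by 2-fold or more. The heme oxygenase HMOX1 was at -2.66, the thioredoxin reductase TXNRD1 at -2.52 and GCLM, a subunit of the enzyme for glutathione synthesis, at -1.78. G2/M and mitosis genes had a median of -0.66 (percentile 1.5; outside the middle 95% of random lists in 11 of 12 alternatives), or -0.44 with median centring over all probes, with 7 of 15 lower and 0 higher by 2-fold; the spindle factor TPX2 was at -1.21 and cyclin CCNA2 at -1.04. G1/S and DNA replication genes had a median of 0.34 (percentile 97.8), which lay outside the middle 95% of random lists in 4 of 12 alternatives, down to percentile 92.4 (median 0.66 with median centring over all probes), with the replicative helicase subunits MCM7 at 0.54 and MCM2 at 0.37. Ribosomal protein genes had a median of -0.38 (percentile 0.605) after loess, but 0.61 with median centring over all probes and 0.39 with median centring over detected probes; they lay outside the middle 95% of random lists in 10 of 12 alternatives, with percentile 4.41 after regression on gene density, gene length and intensity. Outside these lists, the stress-induced cytokine GDF15 was at -3.19, NAMPT, an enzyme of NAD synthesis, at -3.00, and BTG1, an antiproliferative gene, at -2.97. On the higher side were RAB3IP at 2.29, the spliceosomal SNRNP25 at 2.28, SAC3D1 at 2.13, ABCB6 at 2.12, and the linker histone H1-1 at 2.05. IFI30 was at 1.96, RAC2 at 1.92, the mitochondrial co-chaperone HSPE1 at 1.78, NRM at 1.77 and the calcium-binding S100A9 at 1.74.

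The remaining lists in FaDu lay within the middle 95% of the random lists after loess and the main filter. With no filter on dim probes, epithelial genes at -0.31 (percentile 1.46), heat shock response at -0.55 (1.49) and interferon response at 0.17 (98.7) lay outside. With mean intensity above the median, stem cell factors at -1.43 (1.63) and proteases at 0.89 (98.8) lay outside. The main filter had left 4 stem cell and 7 protease members, so these medians rest on fewer genes still. The stem cell median equalled the ratio of MYC (-1.43). The p53 pathway list had a median of 0.059 (percentile 69.5), although the p53 targets GADD45A, SESN2 and CDKN1A (-1.71) were lower. The medians were -0.25 for epithelial junction genes and keratins (15.4), with KRT15 at 2.76 and CLDN7 at -0.96, 0.062 for keratinocyte differentiation (59.3), and 0.24 for proteases and invasion (82.4), with TIMP1 at 1.54 and PLAU at -1.02. They were 0.15 for interferon response (73.4), -0.0063 for HLA and antigen presentation (57.4), 0.065 for WNT signalling (65.4), -0.36 for NOTCH signalling (23.3), with HES1 at -1.40, and -1.01 for stem cell factors (5.49). They were 0.028 for hypoxia and glycolysis (66.5), -0.59 for heat shock response (6.32) and 0.14 for cholesterol and fatty acid synthesis (82.1), the last being -0.605 (15) with mean intensity above the median. Apoptosis regulators had a median of 0.39 (95), with HRK at -2.48 and BID at 1.02. Their median was -0.090 (22.2) with no filter on dim probes and -0.10 (44.6) after regression on gene density, gene length and intensity. Housekeeping genes had a median of -0.28 (15.3) and histone genes of -0.10 (45.4). With median centring over all probes these were 0.26 and 0.42, the epithelial median 0.20 and the HLA median 0.32. Centring on detected probes put these list medians at 0.0423, 0.205, -0.0206 and 0.0995. The epithelial-mesenchymal transition list had 1 measured member, CCN1, at -0.80. With no loess and median centring over all probes, which moved the FaDu genes by a median of 0.24, the split by 2-fold was 666 higher and 391 lower. Centring on detected probes gave 402 and 605. With 1 array there is no replicate check, and no p-value was computed for FaDu.

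In UM-SCC-23 the same question was asked of a laryngeal line. The lists of epithelial junction genes and keratins, of glycolysis and hypoxia genes and of stress response genes had low medians in the miR-34a cells after loess. In the first of these, the members lower by 2-fold were mostly keratins. With median centring over all probes the list medians were 0.15, -0.24 and -0.071. That centring moved the genes by a median of 0.595. Centring on detected probes moved them by 0.0911 and gave list medians of -0.356, -0.745 and -0.575. Among symbol genes above the median intensity, the lowest ratios were those of LTB, a cytokine of the TNF family, at -2.89, and of the basal keratin KRT5 at -2.40. The highest were those of the heat shock gene HSPA1L at 2.20, whose probe may share signal with near-identical HSP70 genes, and of TCEAL9 at 1.98. Of 4415 genes measured, 387 were lower and 312 higher by 2-fold or more, and 5 were lower and 2 higher by 4-fold or more.

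The epithelial junction and keratin list had a UM-SCC-23 median of -0.59 (percentile 0.74) after loess, 0.15 with median centring over all probes and -0.27 (percentile 2.18) with no filter on dim probes. After loess the list had 5 of its 16 measured members lower by 2-fold or more. It lay outside the middle 95% of random lists in 9 of 12 alternatives, with a median of -0.365 (percentile 3.68) after regression on gene density, gene length and intensity. The 5 members lower by 2-fold were the keratins KRT5 (-2.40), KRT18 (-1.81), KRT19 (-1.54) and KRT15 (-1.11) and the integrin ITGB4 (-1.32). KRT17 was at -0.66. Junction and other epithelial members went both ways, with CLDN4 at -0.81, CLDN7 at -0.76, CLDN1 at -0.041, TJP1 at 0.084 and EPCAM at 0.58. Hypoxia and glycolysis genes had a median of -0.88 (percentile 0.04), or -0.24 with median centring over all probes and -0.23 (percentile 2.5) with no filter on dim probes, with 5 of 12 lower and 1 higher by 2-fold. The vasodilator peptide gene ADM was at -1.55, the phosphofructokinase PFKP at -1.27, the hexokinase HK1 at -0.89 and VEGFA at -0.86. In the unfolded protein and amino acid stress list, 7 of 18 measured members were lower and 0 higher by 2-fold. The median was -0.67 (percentile 0.15) after loess and -0.36 (percentile 2) with no filter on dim probes. With median centring over all probes it was -0.071 (percentile 0.08), where the list was low relative to other genes but near 0 itself. Centring on detected probes gave -0.575 (percentile 0.08). SESN2 stood at -1.58, TRIB3 at -1.41, ATF3 at -1.30 and DDIT4 at -1.11, whereas HSPA5 was at -0.0099, ATF4 at 0.096, DDIT3 at 0.10 and CEBPG at 0.58. Other low genes were H1-1 at -2.0, the importin IPO4 at -1.92, the helicase DHX30 at -1.92 and IL6 at -1.92. SH2D3A was at -1.86, the transketolase TKT at -1.78, TNFAIP2 at -1.77, the cell cycle transcription factor MYBL2 at -1.71, and TEAD4, a transcription factor of the Hippo pathway, at -1.68. High genes were TATDN1 at 1.78, the protease inhibitor SLPI at 1.65, UFSP2 at 1.60, the mitochondrial translation factor MTIF2 at 1.59, ARL6IP1 at 1.59 and GNG12 at 1.58. The nucleolar gene NPM1 was at 1.53, ACADM, an enzyme of fatty acid oxidation, at 1.52, TAX1BP1 at 1.52 and S100P at 1.51.

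Among the other lists in UM-SCC-23, NF-kB targets and inflammatory cytokines had a median of -0.53 (percentile 6.58) with 3 of 8 lower by 2-fold or more, 0.0073 (3.13) with median centring over all probes, -0.26 (0.59) with no filter on dim probes and -0.82 (1.62) with mean intensity above the median. Immediate early genes had a median of -0.55 (6.61), with AREG at -1.54, -0.033 (2.82) with median centring over all probes and -0.099 (19.3) with no filter. After regression on gene density, gene length and intensity, medians outside the middle 95% of random lists were reached by NF-kB targets at -0.84 (0.16), immediate early genes at -0.94 (0.035) and keratinocyte differentiation at 0.85 (100). The medians were 0.28 for G2/M and mitosis (85.6), or 0.345 (97.9) with no filter, -0.16 for G1/S and DNA replication (33.6), with MCM2 at -1.21 and MCM7 at -1.15, 0.17 for ribosomal proteins (68), and -0.10 for NRF2 and oxidative stress (34.5). They were -0.084 for the p53 pathway (60.1), with AEN at -1.61 and CDKN1A at -0.85, and -0.19 for epithelial-mesenchymal transition (36.3). Keratinocyte differentiation had a median of 0.305 (92.9), or -0.0015 with no filter on dim probes. Of its 6 measured members, 1 was higher by 2-fold, CSTA at 1.13, and 1 was lower, KRT13 at -1.68. The medians were -0.23 for proteases and invasion (36.2), -0.38 for interferon response (16.4), -0.37 for HLA and antigen presentation (17), -0.23 for WNT signalling (32.6) and -0.79 for stem cell factors (8.95). The stem cell median was 0.067 (76.2) with no filter on dim probes and -0.043 (9.86) with median centring over all probes. Heat shock response had a median of 0.17 (62.8), cholesterol and fatty acid synthesis of -0.45 (11.2), with SREBF2 at -1.20 and FADS2 at -1.15, and apoptosis regulators of 0.057 (59). Housekeeping genes had a median of 0.37 (89.7), or 0.64 (98.9) with mean intensity above the median, and histone genes of -0.20 (30.4). With median centring over all probes, medians below 0 after loess lay above 0 for G1/S (0.50), NRF2 (0.50), p53 (0.45), epithelial-mesenchymal transition (0.43), proteases (0.42), interferon (0.26), HLA (0.29), WNT (0.36), cholesterol (0.19) and histone genes (0.43). That centring put the median of all measured genes at 0.502. On detected probes, centring left each of these list medians below 0, from -0.315 (cholesterol) to -0.000126 (NRF2). There the NF-kB, immediate early and stem cell medians were -0.497, -0.537 and -0.547. In NOTCH signalling 2 members were measured, HES1 at 0.46 and RFNG at -0.77. Markers of other cell types were near absent on both arrays: of 19 fibroblast and endothelial markers 1 was measured in each line, of 17 leukocyte markers 1 in FaDu and 0 in UM-SCC-23, and of 13 neural and embryonic kidney line markers 0 in either. Median centring over all probes moved the UM-SCC-23 genes by a median of 0.595 and gave 1337 genes higher and 36 lower by 2-fold. Centring on detected probes gave 507 and 302. The UM-SCC-23 ratios rest on 1 array and carry no p-value.

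**Figure D1:**
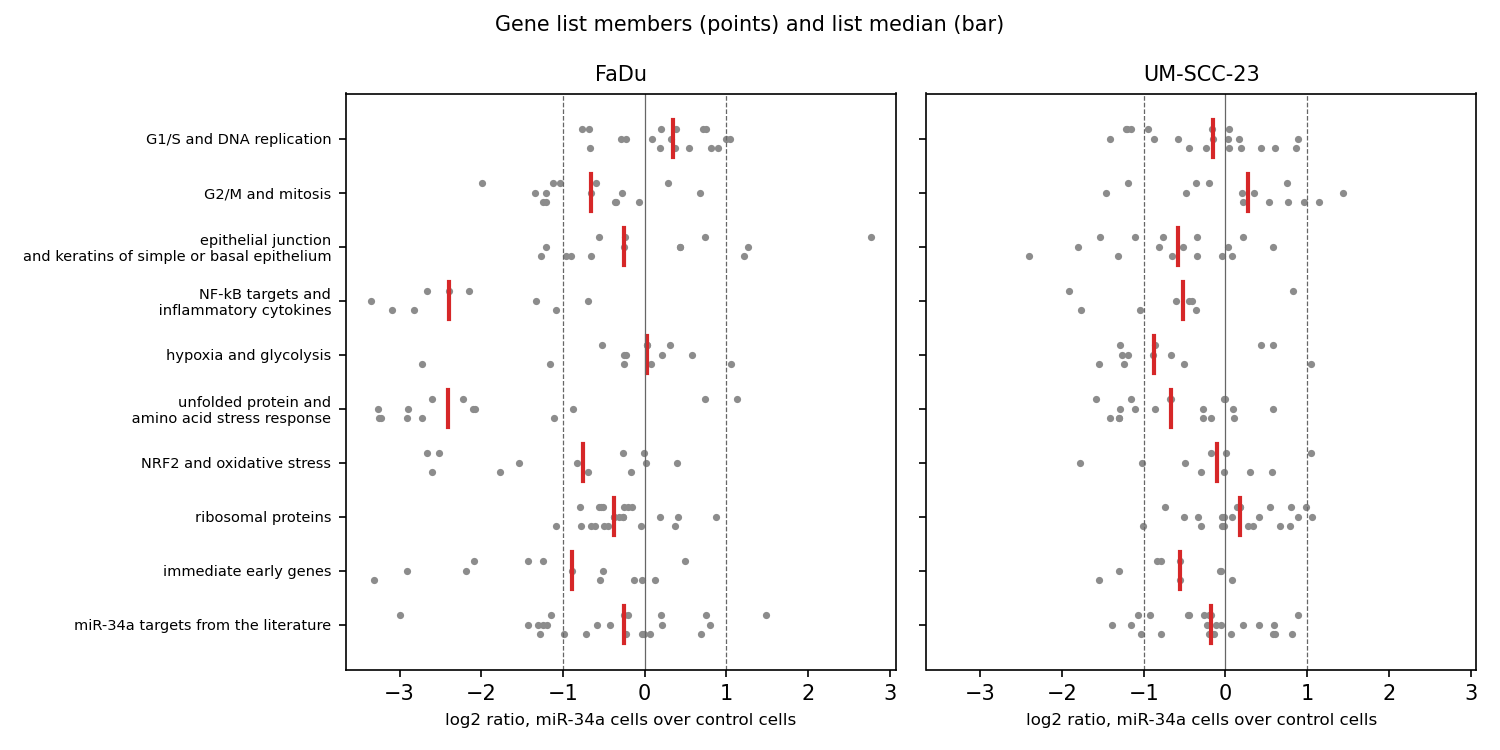
Log2 ratios of miR-34a cells over control cells (x axis) for the measured members of gene lists (points) with each list's median (red bar), after loess, in FaDu (left) and UM-SCC-23 (right); dashed lines mark 2-fold. The stress list has a median of -2.41 in FaDu and -0.67 in UM-SCC-23 (-0.071 with median centring over all probes, -0.575 on detected probes). The literature targets of miR-34a have one of -0.25 and -0.18. With median centring over all probes the UM-SCC-23 epithelial (0.15), literature target (0.445) and NF-kB (0.0073) medians lie above 0. So do the FaDu ribosomal protein (0.61) and epithelial (0.197) medians. Centring on detected probes puts these at -0.356, -0.0587, -0.497, 0.391 and -0.0206.

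Literature targets of miR-34a were followed in both lines, since a microRNA lowers the transcripts that it pairs with. Their median was -0.25 in FaDu (percentile 22) after loess, with 7 of 23 lower and 1 higher by 2-fold, and -0.087 (percentile 17.9) with median centring over all probes. In UM-SCC-23 it was -0.18 (percentile 34.4) after loess and 0.445 with median centring over all probes, with 4 of 25 lower and 0 higher by 2-fold after loess. Centring on detected probes gave -0.305 in FaDu and -0.0587 in UM-SCC-23. With mean intensity above the median required, the FaDu median was -1.20 (percentile 0.215) and the UM-SCC-23 median -0.055 (percentile 41.3). These values rest on fewer targets than the 23 and 25 of the main filter. With no filter on dim probes the medians were -0.092 (5.64) and -0.16 (1.54). Of 22 targets measured in both lines, 10 were below 0 in both and 1 was above 0 in both. Over all 3849 genes measured in both lines, 35.3% had the same sign in both, and the medians of all genes measured in each line were -0.0752 and -0.0912. The receptor tyrosine kinase AXL was at -1.25 in FaDu and -1.39 in UM-SCC-23, and MYC at -1.43 and -0.79. NAMPT was at -3.00 and 0.42, and YY1 at -1.30 and -0.17. FLOT1 was at -1.20 and -0.26, E2F3 at -0.99 and -0.14, and CDK4 at 0.69 and 0.063. After regression on gene density, gene length and intensity, MYC was at -0.61 and -1.96, E2F3 at -0.22 and -0.735, NAMPT at -2.56 and -0.029, FLOT1 at -1.47 and 0.089, and AXL at -1.33 and -1.15. FLOT2, a lipid raft scaffold protein, was at 1.48 in FaDu and -1.03 in UM-SCC-23. CCND1 was at -1.14 in FaDu and above background in Cy5 alone in UM-SCC-23, while CCNE2 was at 0.89 in UM-SCC-23 and not above background in FaDu. MET, JAG1, CDK6 and BCL2 were above background in neither channel of either line, and SIRT1 in the Cy5 channel of UM-SCC-23 alone.

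Across the 2 lines, several stress response genes were among those lower in both. Among symbol genes above the median intensity, in order of the smaller of the 2 ratios, those lower in both included SESN2 (-3.23 in FaDu and -1.58 in UM-SCC-23), AREG (-3.32 and -1.54), GADD45A (-4.07 and -1.53), TRIB3 (-2.61 and -1.41) and ATF3 (-2.90 and -1.30). DDIT4 (-3.26 and -1.11), ITPKC (-2.01 and -1.05), IL1A (-3.35 and -1.04), RCC2 (-1.50 and -1.03), PDLIM1 (-1.72 and -1.03) and GOT1 (-2.13 and -0.97) followed. Higher in both were HSPA1L (1.64 and 2.20), HSPE1 (1.78 and 1.26), the RNA-binding LSM3 (1.23 and 1.19), GCSH (1.09 and 0.94) and DBI (0.81 and 0.80). Smaller ratios above 0 in both belonged to the mitochondrial genes ATP5ME (0.87 and 0.74), NDUFS5 (0.71 and 0.74) and MRPL18 (0.66 and 0.76), to THOC3 (0.95 and 0.73), TXNDC17 (0.90 and 0.68) and CNPY2 (0.84 and 0.65), and to the proteasome assembly factor POMP (0.66 and 1.28). GADD45A was the single gene of 3849 to pass the limma test of the mean over both lines (mean -2.80, SE 0.63, adjusted p = 0.0325, below 0 on 2 of 2 arrays). The SE of 0.63 was the same for every gene, because limma used a spread pooled over all genes, so the test ranked genes by their mean alone. It does not give the precision of GADD45A, whose ratios were -4.07 and -1.53. IL6 (mean -2.51), AREG (-2.43) and SESN2 (-2.41) did not pass, each with a limma adjusted p of 0.124. At an unadjusted p under 0.05 there were 53 genes, against 192 by chance if the 2 lines were independent. Their ratios correlated at -0.344 (Pearson), which widens the spread between lines and narrows that of the means. The count of 192 is therefore not the right one here, and the shortfall says nothing on how much change the lines share. The limma adjusted p of GADD45A ranged from 0.0179 to 1 over 12 alternative settings and was under 0.05 in 4 of them.

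The ratios of the lines ran opposite ways across genes. Over the 3849 genes measured in both, Pearson's r was -0.344 and Spearman's rho -0.382, across genes, which are not independent replicates. The direction was kept because the labels name the dye of each channel on both arrays, and because different lines can respond in opposite ways. The genes named as lower or higher in both lines, the counts of genes moving alike or opposite ways and the limma mean all rest on this labelled direction. Genes past 2-fold in opposite directions numbered 135, of which 44 were higher in FaDu and 91 higher in UM-SCC-23, against 20.6 and 42.0 for independent lists. In the same direction there were 23 lower in both and 5 higher in both, against 50.2 and 17.3. The 5 were HSPA1L, HSPE1, LSM3 and 2 probes with no gene name. KRT15 was at 2.76 in FaDu and -1.11 in UM-SCC-23, H1-1 at 2.05 and -2.0, and S100P at -2.52 and 1.51. The ratios also followed the number of protein-coding genes within 1 Mb, with a Spearman correlation of 0.392 in FaDu and -0.495 in UM-SCC-23 over 2977 genes. With the genes split by this number into 4 groups of near-equal size, the median ratio from the gene-poorest to the gene-richest group was -0.55, -0.19, 0.041 and 0.27 in FaDu, and 0.53, 0.20, -0.31 and -0.53 in UM-SCC-23. Regression on this number, gene length and intensity covered the 3353 FaDu and 3399 UM-SCC-23 genes for which both gene properties were known. Among these, it took the genes past 2-fold from 197 higher and 517 lower to 184 and 348 in FaDu (435 in common). In UM-SCC-23 it took them from 235 and 302 to 108 and 234 (232 in common).

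**Figure D2:**
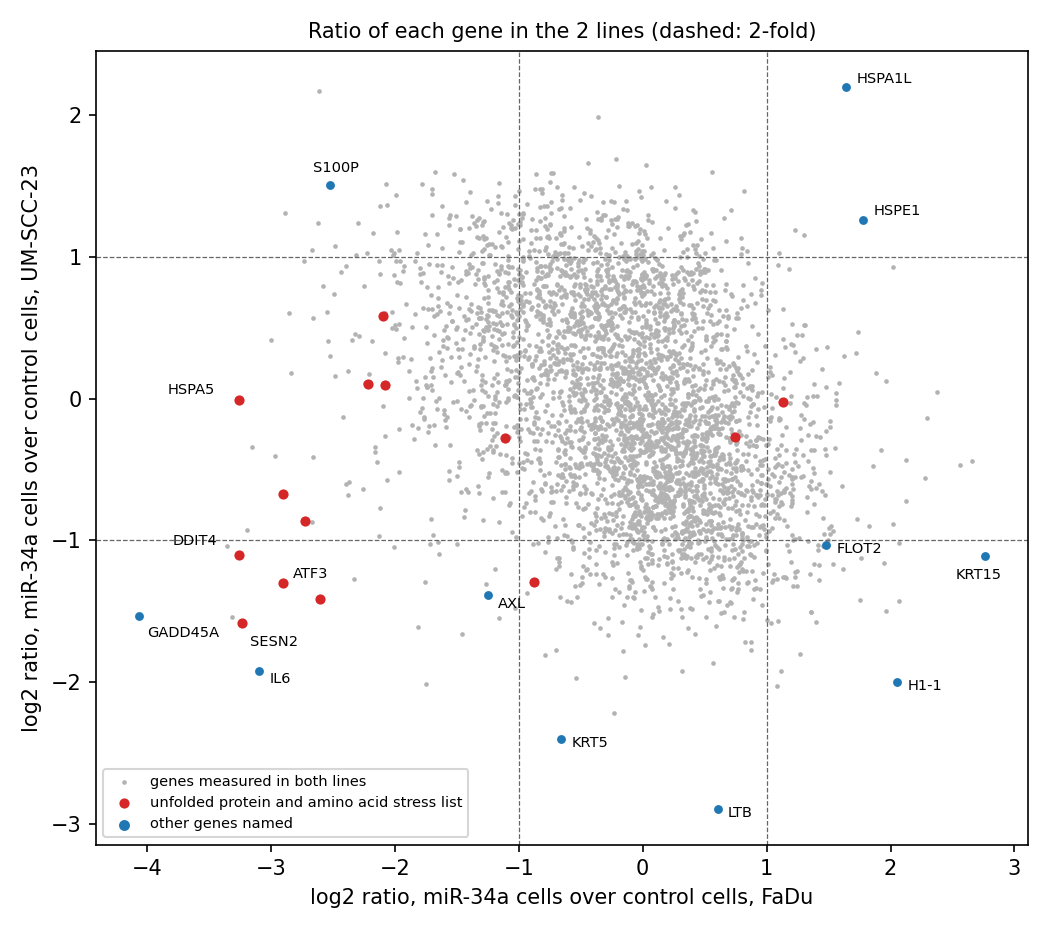
Log2 ratio of miR-34a cells over control cells in FaDu (x axis) and UM-SCC-23 (y axis), with a point for each of 3849 genes measured in both lines; dashed lines mark 2-fold, red points are the stress list and blue points other named genes. The cloud slopes downward (Pearson's r -0.344), while GADD45A (-4.07 and -1.53) and SESN2 (-3.23 and -1.58) lie below 0 on both axes.

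**Figure D3:**
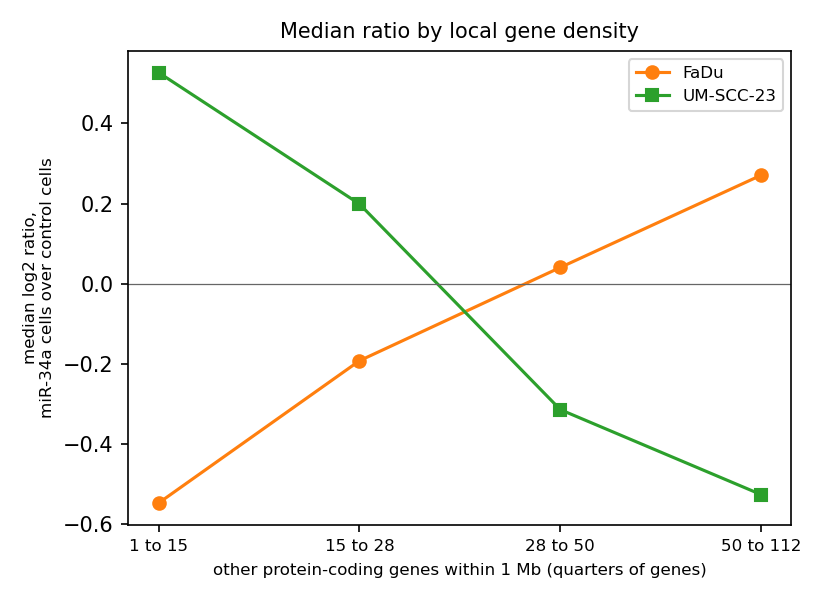
Median log2 ratio of miR-34a cells over control cells (y axis) for 4 groups of near-equal size among 2977 genes ordered by the number of other protein-coding genes within 1 Mb (x axis, range in each group), in FaDu (circles) and UM-SCC-23 (squares). The FaDu median goes from -0.55 to 0.27 and the UM-SCC-23 median from 0.53 to -0.53.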

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

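The tests in this part were chosen after the results they bear on were seen, except the regression of the correlation between lines on gene density and length, whose bounds were written before its result, and the alternative settings for that correlation, most of which were planned.

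The labels put both arrays in the same dye orientation, yet 135 genes were past 2-fold in opposite directions in FaDu and UM-SCC-23; with 1 array per line, no difference between the lines was tested. The FaDu ratio minus the UM-SCC-23 ratio was 3.88 for KRT15, 4.05 for H1-1, 2.89 for NRM, 2.51 for FLOT2, 3.07 for KRT18 and 3.04 for IPO4. It was -2.68 for ACADM, -2.45 for CSTA, -3.10 for GNG12, -3.27 for UFSP2, -3.59 for TAX1BP1 and -4.03 for S100P.

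The background correction, normalization and filter chosen here are argued against as the cause of these opposite ratios. The highest Pearson correlation among the other backgrounds, normalizations, filters and the authors' values was -0.272. The ratios regressed on gene density, gene length and intensity, not counted among these, gave -0.197. An exchange of the Cy5 and Cy3 values of 1 array is argued against by the control spots Y1 to Y8, whose mean ratios, which an exchange would turn over, correlated at 0.998 between the arrays (Y5 at 3.19 and 3.20, Y6 at -2.79 and -2.74), whereas RNAs exchanged before labelling, against the labels, stay open, since a dye effect could have kept the stress genes low in UM-SCC-23 (percentile 0.15). A candidate explanation is a bias with GC content or gene length of opposite sign on the arrays: the ratios correlated with gene density at 0.392 and -0.495 and with gene length at -0.323 and 0.212, and regression on both and on intensity left 46.3% of the covariance. Gene density and length stand in for GC content, as no sequence was used here, and the regression left FLOT2 at 1.40 and -0.85 and KRT15 at 2.28 and -0.60. A difference between the lines in their response to miR-34a stays open and untested.

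Stress response genes had list medians below 0 in both lines, at -2.41 in FaDu and -0.67 in UM-SCC-23 after loess. Of 14 members measured in both lines, 9 were below 0 in both. With median centring over all probes the UM-SCC-23 median was -0.071, low only relative to other genes (percentile 0.08). Centring on detected probes gave -0.575, at the same percentile. A trend with gene density, gene length and intensity as the whole cause is argued against by the regressed ratios, where the list stayed at or below percentile 0.03 of random lists in both lines. A dye effect equal on both arrays would give equal ratios, so it is argued against as the cause of the larger FaDu shift by the median of FaDu minus UM-SCC-23 over 14 members, -1.76 (quartiles -2.21 and -0.92). In FaDu 11 of the 14 (78.6%) were lower, short of the 80% first asked for, and the rule on the quartiles was set after these values were seen. For the shift shared by the lines (-0.67 in UM-SCC-23), a dye effect and miR-34a cannot be told apart, because no dye-swapped array was analysed.

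Spots named "obs", which the tables do not explain, were above background in both channels in 26.6% of cases in FaDu and 25.0% in UM-SCC-23, against 3.82% and 3.97% of blank spots.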

How the results depend on the processing

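The restriction to detected spots combined with the scanner's flag, the omission of saturated spots, centring on detected probes and the regression on gene density were chosen after the data were seen. With median centring without loess, 652 of 894 FaDu genes and 348 of 699 UM-SCC-23 genes past 2-fold stayed past it, as did 84 of 123 calls among named genes. The FaDu stress, NF-kB, NRF2 and immediate early lists and the UM-SCC-23 stress list stayed below percentile 2.5 under all 12 alternatives. A size rule of 1.5-fold by construction gave 708 higher and 1153 lower genes in FaDu and 964 and 1091 in UM-SCC-23. Median centring without loess gave 666 and 391, and 1337 and 36, with medians of 0.609 for FaDu ribosomal proteins and 0.148 for the UM-SCC-23 epithelial list. Centring on detected probes gave 402 higher in FaDu and 507 higher in UM-SCC-23. The same list medians were then 0.391 and -0.356. Plain subtraction gave 459 higher in FaDu (665 lower), the authors' values 400 higher in FaDu, and no filter 569 higher in UM-SCC-23 (464 lower). Requiring mean intensity above the median left 2151 and 2164 genes, with 157 higher and 314 lower in FaDu and 182 and 215 in UM-SCC-23. The limma count of 1 became 2 (GADD45A and AREG) with block loess. It became 0 with a trended robust prior (34 at an unadjusted p under 0.05), plain subtraction (44), normexp without offset (50), median centring (107), no filter (443), the authors' table (50), the scanner flag (46) and centring on detected probes (42). GADD45A alone was -4.07 in FaDu and -1.53 in UM-SCC-23. Spearman's correlation between lines ranged from -0.389 to -0.205, the latter with no filter, and was -0.235 after the regression on gene density, length and intensity. Apart from the changes fixed by construction, the cause was not tested. Signal over background limits the ratios to 20.8% of the gene spots in FaDu and 20.9% in UM-SCC-23. No paired analysis was possible because each line has 1 array and no replicate numbers to use as a block; each ratio already pairs the RNAs of a line, and the limma mean is over these ratios. The test of miR-34a seed sites in 3' untranslated regions and its alternatives were not run, as no sequence was used here.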

Other observations

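The gene families in this part and the tests of aminoacyl-tRNA synthetases in FaDu alone, that of a dye effect included, were chosen after the data were seen; the bounds for the synthetases in both lines were written before their values. The families, apart from the synthetases, were taken by the form of the gene symbol, so that they hold a few genes of other function, such as PSMC3IP among proteasome subunits, EIF2AK2 and EIF4EBP1 among initiation factors and SLC2A4RG and SLC4A1AP among solute carriers. Mitochondrial ribosomal protein genes had a median of 0.395 in FaDu (percentile 100 of random lists; 9 of 55 higher and 1 lower by 2-fold) and 0.14 in UM-SCC-23 (86.5). Respiratory chain and ATP synthase subunits stood at 0.13 (91.6) and 0.45 (99.9), and 20 of 55 were above 0 in both lines. After regression on gene density, length and intensity the mitochondrial ribosomal medians were 0.46 (percentile 100) and -0.025 (59.9), and those of the respiratory chain 0.18 (98.1) and 0.10 (92). Median centring over all probes gave 0.97 and 0.88 for the former and 0.84 and 1.22 for the latter. Keratins had a median of 0.375 in FaDu (95.6) and -1.11 in UM-SCC-23 (0), where 6 of 11 were lower by 2-fold; the UM-SCC-23 median was -0.44 with median centring over all probes, and the regression gave 0.060 (68.2) and -0.74 (0.12). Solute carriers stood at 0.24 (99.6) and -0.46 (0.225), the latter 0.16 with median centring over all probes and -0.341 with centring on detected probes. After the regression they stood at 0.10 (92.8) and -0.23 (7.16), inside the middle 95% in both lines.

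Chaperonin subunits had medians of -0.64 in FaDu (percentile 2.81) and 0.41 in UM-SCC-23 (82.7), and translation initiation factors of -0.41 (2.16) and 0.051 (57.4), the last being -0.034 with block loess; after the regression they were -0.285 (19.8) and 0.27 (83.6), and -0.385 (1.59) and -0.0030 (59.5). With median centring over all probes they were -0.19 (1.33) and 1.21 for chaperonins, and -0.082 (0.52) and 0.68 for initiation factors. All cytosolic ribosomal protein genes had medians of -0.17 (5.10), which was 0.76 with median centring over all probes, and 0.41 (99.3); after the regression they were -0.035 (54.3) and 0.079 (89.1). Proteasome subunits stood at -0.21 (10.5), or 0.49 with that centring, and 0.38 (96.1); after the regression they stood at -0.078 (37.2) and 0.30 (99.2). S100 protein genes stood at 0.062 (70.5) and 0.35 (91.7), and zinc finger genes at -0.26 (8.94) and -0.10 (45.7), the latter 0.62 with that centring; after the regression they stood at -0.15 (32.9) and 0.89 (100), and -0.15 (27.2) and 0.14 (94.1).

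Lower output of the ATF4 programme was tested as a hypothesis for the low stress genes, using cytosolic aminoacyl-tRNA synthetases known as ATF4 targets, none of which is on the stress list. In FaDu 8 of 8 were lower by 2-fold or more, with a median of -2.24 (percentile 0.01), and in UM-SCC-23 the median was 0.24 (percentile 70.6). The synthetase gene GARS (mean over both lines -1.75) kept its older name and was in neither group of synthetases. As the 8 lay on both sides of 0 in UM-SCC-23, a further member could change the sign of that median. The UM-SCC-23 median of the 8 passed the bound set for arguing against a programme lowered in both lines, but that bound left out the spread. The members went both ways (quartiles -0.649 and 0.96, 4 of 8 below 0 in both lines), and the median after regression on gene density, length and intensity was -0.11 (34.4). On the stress list, ATF4 itself was at -2.08 in FaDu and 0.096 in UM-SCC-23, while its target TRIB3 was at -2.61 and -1.41. Lower ATF4 output in UM-SCC-23 therefore stays open. In FaDu alone the median lay -2.11 from that of the 5 other cytosolic synthetases measured (-0.13, percentile 44.2, or 0.11 with median centring over all probes; 0.61, percentile 90.2 in UM-SCC-23). A dye effect equal on both arrays is argued against here, as the median of FaDu minus UM-SCC-23 over the 8 was -2.31 (quartiles -3.27 and -1.68). Lower ATF4 output in FaDu is consistent with the difference of -2.11, while a difference between the cultures other than miR-34a stays open with 1 array; the FaDu median after the same regression was -1.91 (percentile 0).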
